A study of Homo sapiens with 10 samples.

How the data were processed

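RNA of HuH-7 cells kept for 96 h with 1 µM lenvatinib or without it was labelled with Cy5 and hybridised to 3D-Gene miRNA arrays, 1 colour and 1 array per sample, per the labels' protocols. The labels give 5 control and 5 lenvatinib arrays, and each array was placed in its group by its own label. The extraction protocol in the labels names serum and a reagent for liquid samples, while the source labels name the cell line. The scanner, its software, the slide and the scan date are not given in the sources used here.

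Each deposited array file holds 3 intensity columns on a linear scale, per the file headers: raw brightness, a background-subtracted value and a globally normalized value. How the authors made the last 2 columns was worked out from the values. Background-subtracted intensity in the deposited files equalled raw brightness minus 1 value per array, the mean of the blank spots after trimming 5% at each end, and was left empty unless raw brightness exceeded that mean by 2 SD. This detection rule matched the filled and empty cells of all 2565 miRNA probes on each of the 10 arrays. The globally normalized intensity in the deposited files was the subtracted value times 1 factor per array that set the median to 25. The deposited table of the whole series held linear intensities of 803 of 2565 probes, with sorted columns that differed by at most 0.1 and a median of 24.3 in each column, as quantile normalization leaves them. Its values ranked as those of the matching array did, with a Spearman correlation of 0.999998 over probes. The table's scale is linear and its values are not centred. The 803 probes were all detected on all 10 arrays, and another 65 probes detected on all arrays were left empty there.

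For the main analysis the background-subtracted intensities were used as deposited, spots marked NG in the files were left out (10 miRNA spots on lenvatinib replicate 5, 2 on control replicate 5 and 1 on lenvatinib replicate 1), and undetected probes were set to the lowest detected value of their array. Values were then put on the log2 scale and quantile normalized between arrays. Blank and control spots were left out. The 1346 probes detected on at least 5 of the 10 arrays were tested with limma (lmFit and eBayes, two-sided) without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. Log2 fold changes are lenvatinib minus control with their standard errors, and every adjusted p of a single miRNA comes from limma. A probe detected on no array of 1 group and on all 5 of the other has only a nominal bound there. It is the mean of the brighter group over the mean of the dim group's lowest detected values, after normalization. Those lowest values sit on the floor given to undetected probes, so it is the fold over that floor and not a strict lower limit.

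The test, the samples, the lists, the naming rule and most of the alternative settings were chosen before the data were examined. The rule named the 10 largest rises and the 10 largest falls among miRNAs that passed, whose 5 lenvatinib values all lay on 1 side of the 5 control values and which were detected on all 5 arrays of the brighter group. It also named miR-122-5p, miR-21-5p, miR-210-3p, miR-34a-5p and let-7a-5p, up to 4 members of each list with the smallest p, and up to 3 probes with a bound. The 23 lists were the let-7, miR-15/16, miR-29, miR-30 and miR-200 families, the miR-17 and miR-23/27/24 clusters, the C19MC and 14q32 clusters, p53-responsive, hypoxia-responsive and RTK/ERK/CREB-responsive miRNAs, those raised or lowered in hepatocellular carcinoma, hepatocyte-enriched, angiogenesis and VEGF, and lipid metabolism miRNAs, markers of erythroid, leukocyte, muscle, neural, and endothelial and stromal cells, and miRNAs numbered 3000 and above in miRBase. The miR-200 list also held miR-205-5p, which is not a member of that family. Lists with at least 3 tested members were compared with the other miRNAs by camera (preset correlation 0.01, two-sided). Camera took only members with a value on all 10 arrays, which left out members with an NG spot: it covered 14 of 16 tested members of the miR-17 clusters, 7 of 8 hypoxia-responsive, 14 of 18 lowered in hepatocellular carcinoma, 16 of 17 angiogenesis, 7 of 8 in the miR-23/27/24 clusters, 5 of 7 in the miR-30 family and 6 of 7 lipid metabolism miRNAs, and all tested members of the other 16 lists. No list passed with a correlation estimated per list. With fry, which tests whether the members of a list move on balance 1 way and does not compare them with other miRNAs, 11 lists passed.

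Array measures were compared with exact two-sided permutation tests over all 252 ways to split the arrays 5 and 5, whose smallest possible p is 0.00794. These 7 measures formed 1 family, and their Benjamini-Hochberg adjusted p was 0.00926 for the 6 with that p and 0.643 for the number of detected probes. The alternative settings covered background correction (normexp with an offset of 50, or none), scaling (median, 75th percentile, cyclic loess or none), the filter on dim probes, the authors' normalized table, a replicate block, eBayes with trend and robust fitting, array quality weights, an exact rank test, the detection limit, and leaving out each array in turn. Scaling to the spike controls, the authors' global normalization and keeping the NG spots were added after seeing the data.

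The fitting steps were tested on simulated data for 1334 probes. They called 77 of 96 probes changed 2-fold (80.2%) and 92 of 93 changed 4-fold (98.9%), and 17 of 186 calls were false (9.14%), more than the nominal 5%. For the lists, a raised list had an adjusted p of 3.07e-09 and 0 of 20 random lists passed, in data simulated without correlation between miRNAs. Positions of miRNA genes in GRCh38.p14 served only to tell which genes neighbour each other. The analysis used R 4.3.3, limma 3.58.1, jsonlite 2.0.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.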

Results

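MicroRNA (miRNA) levels were measured in HuH-7, an established human hepatocellular carcinoma cell line, kept for 96 h with or without 1 µM lenvatinib, an oral inhibitor of the VEGF and FGF receptor tyrosine kinases. The series holds 10 single-colour arrays, 5 labelled control and 5 labelled lenvatinib, numbered 1 to 5 in each group. The stated purpose was to find miRNAs tied to the antitumour action of lenvatinib in this line. The extraction label speaks of serum while the other labels describe cultured cells, so the values are those of samples as labelled. No label says whether the 5 arrays of a group came from separate cultures, and the p-values therefore measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

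Each array carried 2565 miRNA probes, of which 868 were detected on all 10 arrays and 641 on none. Control arrays detected 1359.6 ± 125 miRNA probes (SD, n = 5) and lenvatinib arrays 1324 ± 121 (SD, n = 5), a difference of -35.6 that lay within the spread between arrays (exact two-sided permutation test, p = 0.643). With 1 raw intensity limit for all arrays in place of each array's own limit, the lenvatinib arrays detected 405.8 more (exact permutation test, p = 0.00794). Blank spots, which carry no probe, were brighter on every lenvatinib array, at 68.0 ± 9.88 intensity units (SD, n = 5) against 33.3 ± 1.51 (SD, n = 5), a ratio of 2.04 (exact permutation test, p = 0.00794, the smallest p that 5 against 5 can give). The 2 kinds of spike control spots were higher by 1.21 and 1.26 on the log2 scale and the median of the miRNAs detected on all arrays by 1.35, with the same p. The 10 brightest miRNAs took 58.2% ± 0.619 of the signal on control arrays (SD, n = 5) and 43.4% ± 1.5 on lenvatinib arrays (SD, n = 5). Unlike the spike controls and the median, the brightest probe, miR-4454, overlapped between the groups. Its background-subtracted signal was 40558.1 to 46534.7 on control arrays and 36760.5 to 50778.8 on lenvatinib arrays. The smaller share alone therefore does not show a change in miRNA composition. Because the blank levels of the groups did not overlap, the session or scan of an array and the treatment cannot be told apart in these data. Lenvatinib replicate 5 had the brightest blanks, at 85.5, and correlated with the other lenvatinib arrays at 0.938 to 0.947 over the tested probes, against 0.967 to 0.981 among the other 4.

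**Figure D1:**
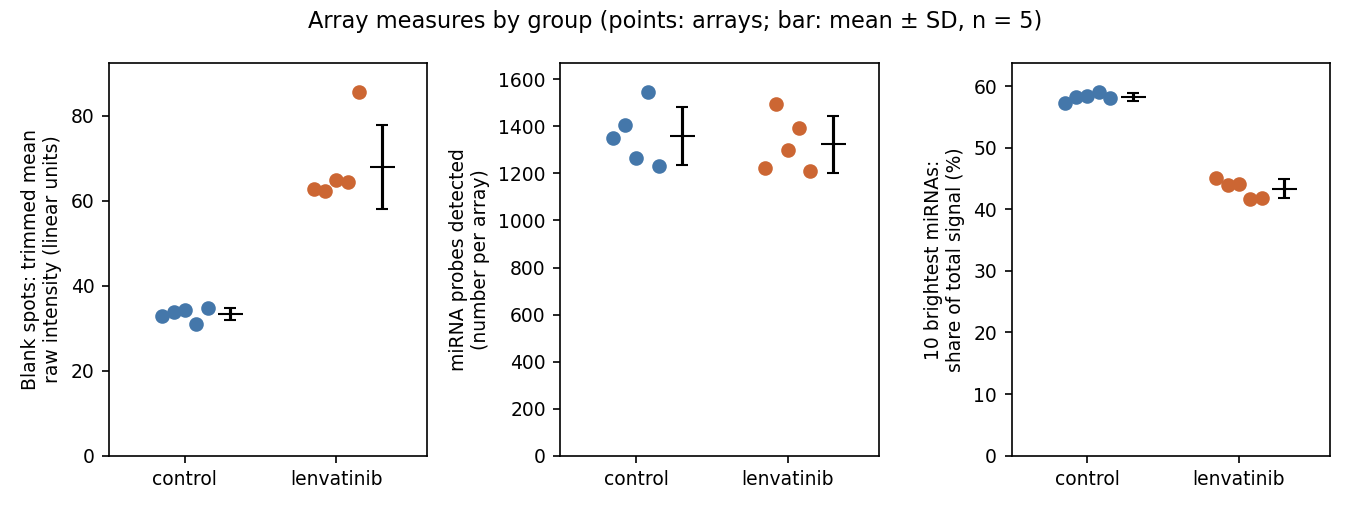
Each panel plots 1 array measure on a linear axis from 0 for the 5 control and 5 lenvatinib arrays (points), with the group mean ± SD beside them. Blank spot intensity was 30.9 to 34.6 on control arrays and 62.2 to 85.5 on lenvatinib arrays, detected probes overlapped between the groups, and the 10 brightest miRNAs took a smaller share of signal on lenvatinib arrays.

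After quantile normalization, miR-7-5p, which represses EGFR, was 4.27-fold lower on the arrays of lenvatinib-treated cells (log2 change -2.09 ± 0.25, SE, 5 against 5 arrays), and miR-29b-3p, which represses collagen genes, was 4.09-fold lower (-2.03 ± 0.16). Several miRNAs known to be raised in hepatocellular carcinoma were lower too, among them miR-224-5p, miR-130b-3p and miR-21-5p. In the other direction, miR-1185-1-3p was 4.05-fold, miR-4294 3.61-fold and miR-642b-3p 3.60-fold higher, and miR-210-3p, the best known hypoxia-induced miRNA, was 1.59-fold higher. In total, 289 of 1346 tested probes passed an adjusted p of 0.05 (limma, 5 against 5 arrays), 163 of them higher and 126 lower with lenvatinib, and 78 changed at least 2-fold, 45 up and 33 down. The 5 lenvatinib values lay wholly above or below the 5 control values for 269 tested probes (19.99%, where chance gives 0.794%).

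The split of calls depends on the scaling of the arrays. Calls numbered 117 higher and 250 lower after scaling to the 75th percentile, which moved the median change of all tested probes to -0.18 on the log2 scale, and 190 higher and 85 lower after scaling to the spike controls. With no scaling, there were 928 calls higher and 2 lower, the median change was 0.86, and 23 of the 69 miRNAs tracked across settings changed sign, among them miR-21-5p, miR-29a-3p and miR-29c-3p. Every direction given here is therefore relative to the bulk of the miRNAs. Sizes depend on the handling of background, since with normexp correction and an offset of 50, which compresses dim signals, 41 of the 69 changes shrank by over 1.5 times, while 67 of 69 stayed on their side of the threshold. MiR-29b-3p was then at -1.63 and miR-7-5p at -1.47, but miR-224-5p at -0.27, miR-4294 at 0.66 and miR-1185-1-3p at 0.27.

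Among the falls, miR-7-5p had an adjusted p of 0.000220 and miR-29b-3p 1.98e-05. MiR-130b-3p, from a cluster often raised in liver cancer, changed by -1.70 ± 0.21 on the log2 scale (SE, adjusted p = 0.000246), and miR-146a-5p, an NF-kappaB-induced feedback inhibitor of TRAF6 and IRAK1, by -1.64 ± 0.38 (adjusted p = 0.0102). Both arms of the miR-224 hairpin were lower, miR-224-5p by -1.5 ± 0.22 (adjusted p = 0.000569) and miR-224-3p by -1.72 ± 0.56 (adjusted p = 0.0468). The size of the miR-224-3p change rested on control replicate 5, without which it was -1.08 (adjusted p = 0.00304), and its adjusted p ran from 0.00304 to 0.447 over 27 alternatives, of which 15 kept the call. The other 4 of the 10 largest falls under the naming rule were miR-6765-3p, miR-148a-5p, miR-590-5p and miR-140-5p, with log2 changes from -1.47 to -1.34. The change of miR-590-5p was -0.92 without lenvatinib replicate 5 (adjusted p = 0.00151), and its call was lost when any control array or lenvatinib replicate 4 was left out, with adjusted p from 0.00151 to 0.969 over 27 alternatives, of which 14 kept the call. With no scaling, only miR-7-5p and miR-29b-3p of these 10 kept their call.

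Among the rises, miR-1185-1-3p, from the imprinted 14q32 miRNA cluster, changed by 2.02 ± 0.20 on the log2 scale (SE, adjusted p = 0.000124), although it was detected on only 3 of the 5 control arrays. MiR-4294 changed by 1.85 ± 0.14 (adjusted p = 1.98e-05). MiR-642b-3p and miR-642a-3p, whose sequences are nearly identical and whose probes may share signal, changed by 1.85 ± 0.20 and 1.52 ± 0.23. The other 6 of the 10 largest rises were miR-3131, miR-3928-3p, miR-1247-3p, miR-6816-5p, miR-3180-3p and miR-1290, with log2 changes from 1.59 to 1.42. MiR-3131 and miR-3928-3p were detected on 3 of the 5 control arrays and miR-1290 on 2, so their sizes, like that of miR-1185-1-3p, depend on the value given to undetected probes, and their order is not resolved. Probes for miR-4787-3p and miR-4465 were detected on no control array and all 5 lenvatinib arrays. Under the main settings they lay 2.54-fold and 2.07-fold above the floor given to undetected probes (adjusted p = 0.000459 and 0.00309). With normexp correction their changes were only 0.17 and 0.12 on the log2 scale (adjusted p = 0.00312 and 0.00967). The probe shared by miR-199a-3p and miR-199b-3p had the same detection pattern, with a log2 change of 0.89, an adjusted p of 0.0613 and a pass in 7 of 25 alternatives. That size rested on lenvatinib replicate 1, at 3.84 against 1.88 to 2.62 on the other 4, without which it was 0.56 (adjusted p = 0.0354), and with normexp correction it was 0.15 (adjusted p = 0.0416).

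Of the 5 miRNAs named in advance, miR-210-3p was higher by 0.67 ± 0.15 on the log2 scale (SE, adjusted p = 0.00820) and miR-21-5p, an oncogenic miRNA, was lower by a change of -0.59 ± 0.15 (adjusted p = 0.0165), between quantile values tied on 4 of the 5 control arrays. The size for miR-21-5p depends on the scaling, at -0.99 after scaling to the median, -1.14 to the 75th percentile and 0.37 with no scaling. MiR-122-5p, the dominant hepatocyte miRNA, stood 0.35 ± 0.10 higher (adjusted p = 0.0314), between quantile values tied on 3 control and 3 lenvatinib arrays. Its sign turned after scaling to the median (-0.043) or to the 75th percentile (-0.20). Its call was lost on leaving out any array but lenvatinib replicate 5 (adjusted p from 0.0551 to 0.0657, and from 7.53e-07 to 0.913 over 27 alternatives, of which 12 kept the call). MiR-34a-5p, a p53 target, differed by 0.20 ± 0.12 (adjusted p = 0.292), by 0.12 without lenvatinib replicate 5, and passed in 5 of 27 alternatives, among them scaling to the median at 0.44 (adjusted p = 0.0287, range over the alternatives 9.40e-08 to 0.398). Let-7a-5p differed by -0.09 ± 0.21 (adjusted p = 0.815), less than the spread between arrays.

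**Figure D2:**
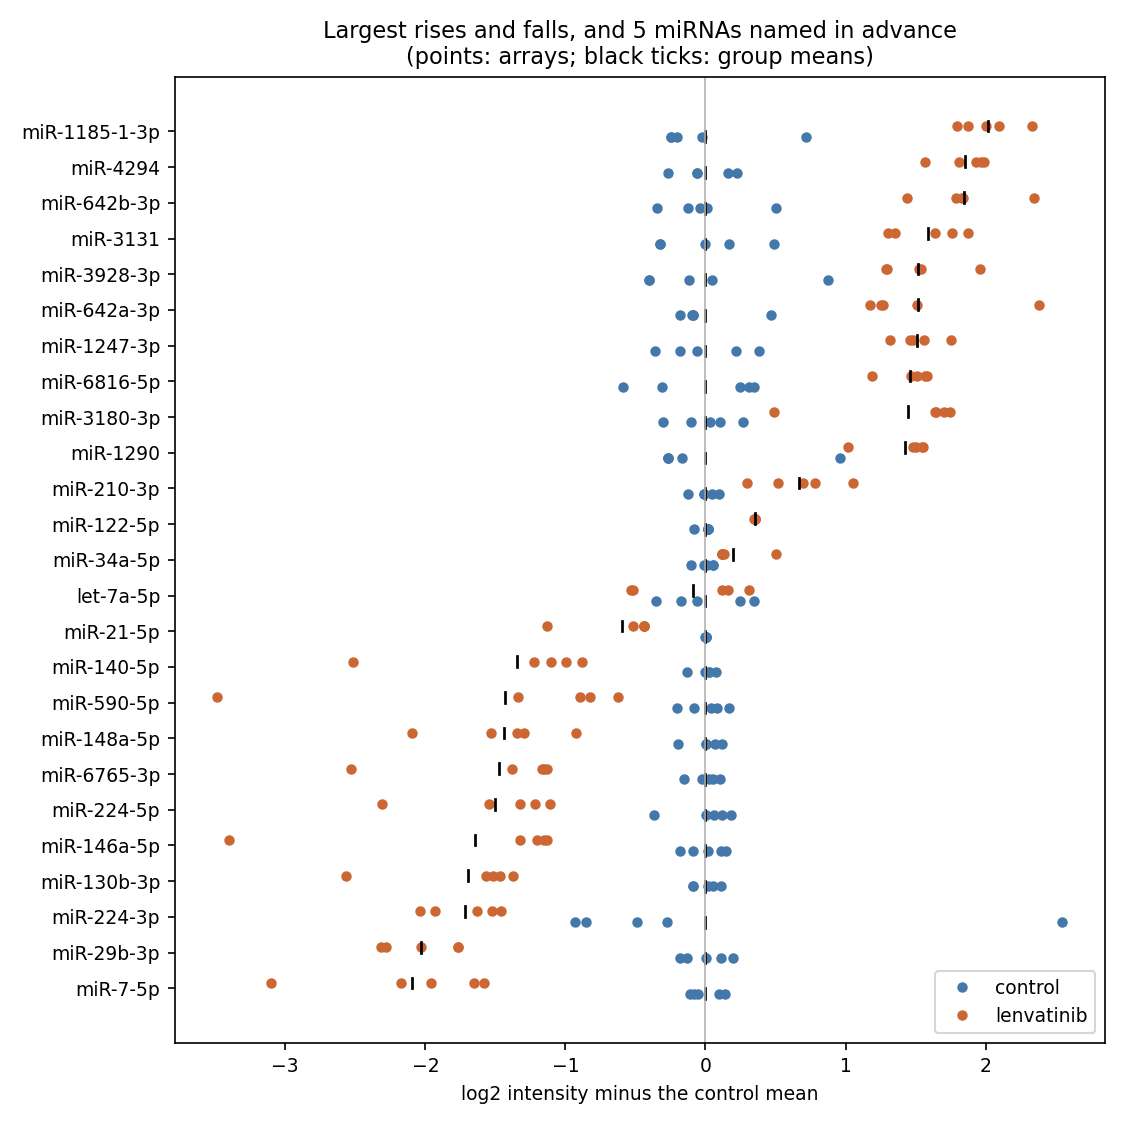
The horizontal axis gives log2 intensity minus the control mean for the 10 largest rises, the 10 largest falls and the 5 miRNAs named in advance; points are the 5 control and 5 lenvatinib arrays and black ticks the group means. Mean changes ran from -2.09 for miR-7-5p to 2.02 for miR-1185-1-3p, and 1 lenvatinib array lay far from the other 4 for miR-146a-5p and miR-590-5p.

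Among 23 lists of miRNAs, 7 passed camera at an adjusted p under 0.05, 4 of them downward and 3 upward, on arrays whose blank spots differed between the groups by a ratio of 2.04. In the miR-29 family, which restrains extracellular matrix genes, 0 of 7 tested members rose and 4 fell, also 4 adjusted over the list alone (camera adjusted p = 0.00470, and adjusted p = 0.156 with an estimated correlation). MiR-29b-3p was joined there by miR-29c-3p at -1.10, miR-29a-3p at -0.74 and miR-29b-1-5p at -0.73, and the call of miR-29c-3p held in 18 of 27 alternatives. In the miR-17 clusters, driven by MYC and E2F in proliferating cells, 0 of 16 rose and 7 fell, also 7 adjusted over the list alone (camera on 14 of them, adjusted p = 0.00470, and adjusted p = 0.169 with an estimated correlation). Changes there were -0.95 for miR-106b-3p, -0.92 for miR-17-3p, -0.74 for miR-18a-5p and -0.69 for miR-19b-3p, and the calls of miR-17-3p and miR-19b-3p each held in 24 of 27 alternatives. The 9 members that did not pass included miR-17-5p at -0.20, miR-20a-5p at -0.12, miR-106a-5p at -0.0005 and miR-25-3p at 0.004. Members of these clusters thus did not all change alike. MiR-19b-3p had 4 lenvatinib values, as the spot on replicate 5 was marked NG, and with that spot kept it was at -1.12 and did not pass (adjusted p = 0.0529). Of 18 miRNAs known to be raised in hepatocellular carcinoma, 1 rose and 8 fell, and 1 and 10 when adjusted over the list alone (camera adjusted p = 0.00929, and adjusted p = 0.156 with an estimated correlation). MiR-130b-3p, miR-224-5p and miR-452-5p, at -0.93, were among the falls, and miR-210-3p was the rise. Of 7 miRNAs responsive to receptor tyrosine kinases, ERK or CREB, 0 rose and 3 fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.156 with an estimated correlation). These 3 were miR-21-3p at -0.96, miR-21-5p at -0.59 and miR-221-3p at -0.44, whose call held in 19 of 27 alternatives. This list's camera call held in 15 of 26 alternatives.

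Of 11 p53-responsive miRNAs, 5 rose and 0 fell, also 5 and 0 adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.156 with an estimated correlation). The rises included miR-215-5p at 0.96, miR-194-5p at 0.59 and miR-34b-5p at 0.57. MiR-194-5p lost its call after scaling to the median (0.29), the 75th percentile (0.14), cyclic loess (0.30) and with the authors' global normalization (0.31), and miR-34b-5p after scaling to the 75th percentile. Of 8 hypoxia-responsive miRNAs, 4 rose and 0 fell, also 4 and 0 adjusted over the list alone (camera on 7 of them, adjusted p = 0.0288, and adjusted p = 0.156 with an estimated correlation). They were miR-193b-3p at 0.82, miR-210-3p, miR-424-5p at 0.54 and miR-107 at 0.41, and miR-107 turned to -0.083 after scaling to the 75th percentile and kept its call in 20 of 27 alternatives. In the list for the miR-200 family, which maintains the epithelial state, 2 of 6 rose and 0 fell, and 4 rose adjusted over the list alone (camera adjusted p = 0.0250, and adjusted p = 0.156 with an estimated correlation). These counts include miR-205-5p, which is not a family member, at 0.82 (limma adjusted p = 0.0795). The 2 that rose were miR-200b-3p at 0.92 and miR-200a-3p at 0.56, and the call of miR-200a-3p held in 12 of 27 alternatives. The p53-responsive list did not pass after scaling to the median (adjusted p = 0.0667), the 75th percentile (0.0562) or cyclic loess (0.0641), nor did the hypoxia-responsive list (0.157, 0.122 and 0.0847), and over 26 alternatives they passed in 21 and 18. After scaling to the median or the 75th percentile, 4 lists passed, the miR-29 family, the miR-17 clusters, the miR-200 family and the miRNAs raised in hepatocellular carcinoma. With no scaling the medians of the 4 lists that fell were above 0, from 0.37 to 0.80. The lists share members, since 44 miRNAs sat in more than 1 list.

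**Figure D3:**
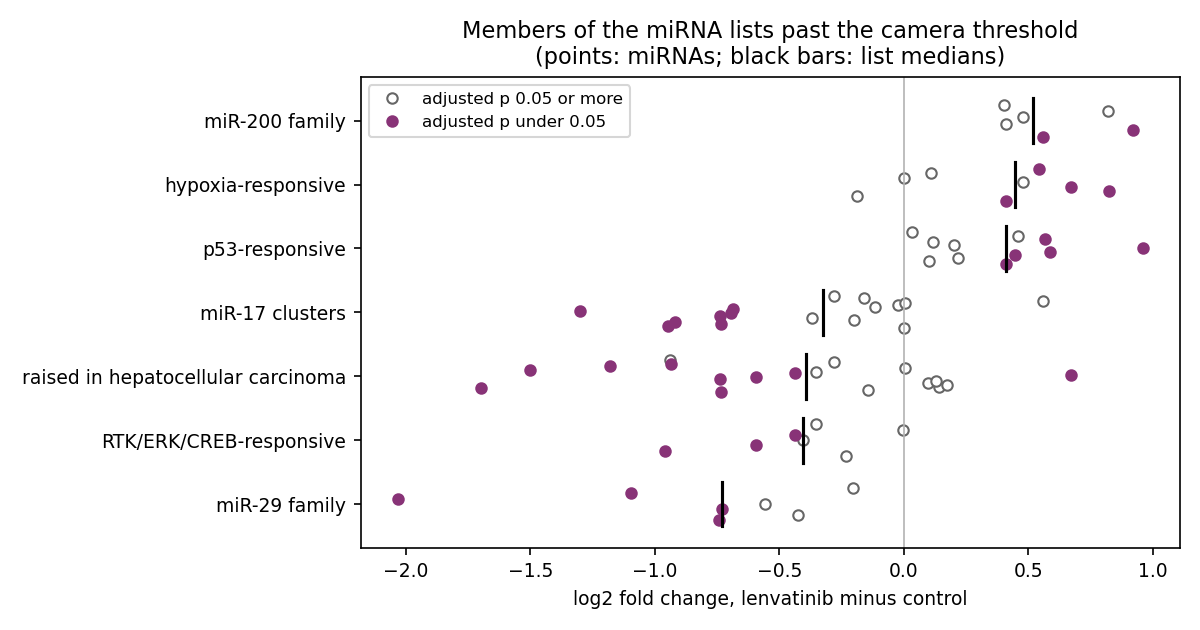
Each point is 1 tested miRNA of the 7 lists that passed, placed at its log2 fold change (lenvatinib minus control, horizontal axis); filled points passed an adjusted p of 0.05 and black bars are list medians. Medians ran from -0.73 for the miR-29 family to 0.52 for the miR-200 family.

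The other 16 lists did not pass camera. In the miR-15/16 family, which restrains the cell cycle, 3 of 7 rose and 1 fell, also 3 and 1 adjusted over the list alone (camera adjusted p = 0.122), with miR-16-5p at 0.83, miR-424-5p at 0.54 and miR-503-5p at 0.52 against miR-497-5p at -0.60, whose call held in 14 of 27 alternatives. This list passed upward in 5 of 26 alternatives (lowest adjusted p = 0.00933), among them normexp and no background correction, and miR-16-5p lost its call after scaling to the median (0.36), the 75th percentile (0.21) and with the authors' global normalization (0.38). The hepatocyte-enriched list split, with 3 of 10 up and 3 down, and 3 and 4 adjusted over the list alone (adjusted p = 0.294), miR-885-5p at -1.22 and miR-378a-3p at -0.87 among the falls. Of miRNAs tied to angiogenesis and VEGF signalling, 5 of 17 rose and 1 fell, also 5 and 1 adjusted over the list alone (adjusted p = 0.294), with a median of -0.02 against a mean of 0.11 and an upward test, which passed only with no scaling (adjusted p = 0.0111). Of those known to be lowered in hepatocellular carcinoma, 2 of 18 rose and 3 fell, and 3 and 3 adjusted over the list alone (adjusted p = 0.913), with a median of 0.03 against a mean of -0.10 and a downward test. The miR-23/27/24 clusters had 2 of 8 up and 0 down, and 4 and 1 adjusted over the list alone (adjusted p = 0.640). The miR-30 family had 1 of 7 up and 2 down, and 1 and 3 adjusted over the list alone, and the lipid metabolism list 1 of 7 up and 1 down, and 1 and 2 adjusted over the list alone (adjusted p = 0.294 for each). In the let-7 family let-7g-5p rose, at 0.99 (not past the exact rank test), among 8 tested members, also 1 adjusted over the list alone (adjusted p = 0.913). In the list for the 14q32 imprinted cluster, which does not hold miR-1185-1-3p, miR-487b-3p fell, at -1.02, among 14 tested members, also 1 adjusted over the list alone (adjusted p = 0.162). Outside the list, where miR-1185-1-3p rose, miR-377-5p (-0.99), miR-487b-5p (-0.65) and miR-656-5p (-0.63), other arms of listed miRNAs, passed downward. Of the primate cluster C19MC, 0 of 10 members passed by either count (adjusted p = 0.637).

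Markers of other cell types did not pass as groups. By both counts, over all miRNAs and adjusted over the list alone, 0 of 3 erythroid, 0 of 3 muscle and 0 of 7 endothelial and stromal miRNAs passed, against 1 up and 1 down of 5 leukocyte and 1 up of 5 neural miRNAs. Their adjusted p was 0.968 for the erythroid, 0.351 for the muscle, 0.802 for the endothelial and stromal, 0.888 for the leukocyte and 0.888 for the neural list. The erythroid median was 0.03 against a mean of -0.09 and a downward test, and the neural median 0.13 against a mean of -0.03 and an upward test. Among miRNAs numbered 3000 and above in miRBase, 96 of 751 rose and 56 fell, and 95 and 55 adjusted over the list alone (adjusted p = 0.134), and that list passed upward in 3 of 26 alternatives.

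**Figure D4:**
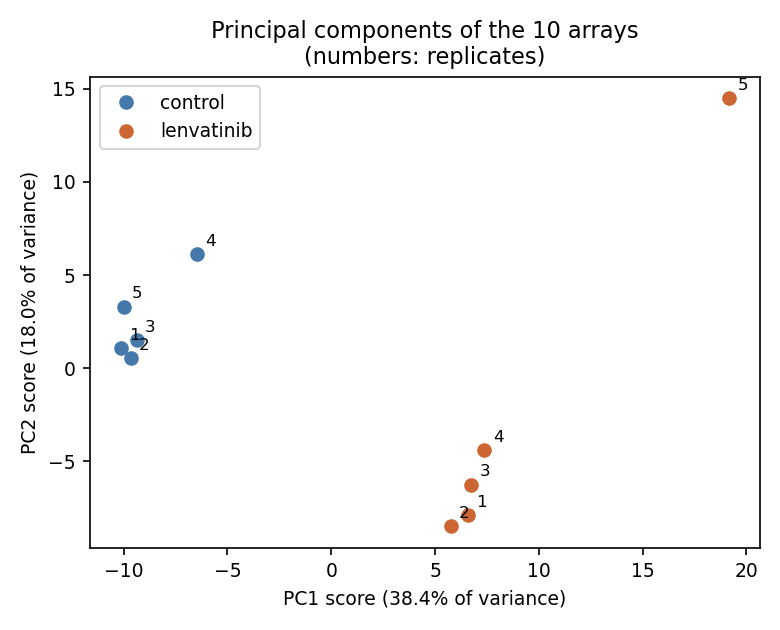
Scores of the 10 arrays on the first (horizontal, 38.4% of variance) and second (vertical, 18.0%) principal components of the tested miRNAs, with replicate numbers beside the points. Control arrays lay between -10.1 and -6.46 on the first component and lenvatinib replicates 1 to 4 between 5.75 and 7.37, while lenvatinib replicate 5 lay at 19.2.

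Lenvatinib replicate 5 stood apart from the other lenvatinib arrays, so the counts were also taken without it. They came to 336 miRNAs past the threshold, 184 higher and 152 lower, 266 of them shared with the 289, and to 6 lists.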

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

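All tests of explanations in this part were chosen after the results they bear on were seen, except the counts over other splits of the arrays. A sample was singled out where its gap to the nearest other array of its group took up most of the group's range (Dixon's 95% criterion), which chance gives in about 1 in 20 groups. Of 150 groups of 5 arrays, over 69 miRNAs and 7 array measures, 33 had such an array, and in 23 of these it was lenvatinib replicate 5. In 9 of the 33, 5 of them on lenvatinib replicate 5, 3 or 4 of the other arrays shared 1 tied value. The tie came from the floor given to undetected probes for miR-1290 on control arrays and from quantile normalization for the other 8, miR-21-5p, miR-122-5p and miR-107 on control arrays and miR-21-5p, miR-34a-5p, miR-122-5p, miR-424-5p and miR-16-5p on lenvatinib arrays.

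The blank spots were 2.04 times as bright on lenvatinib arrays, and the spike controls were higher by 1.21 and 1.26 on the log2 scale, although neither carries sample miRNA. A single brightness factor per array cannot account for the calls between the groups, as scaling to the median gave 167 calls higher and 146 lower, 255 of them shared with the 289. After cyclic loess, which removes a smooth distortion with brightness, there were 312 calls, 270 of them shared. Quantile normalization had already removed a single factor and evens out smooth distortions with brightness as well, so both checks were largely settled beforehand. Neither check covers scan effects that differ between probes of like brightness. For the calls, a chance split of these 10 arrays is argued against. Of 100 splits only 1, the real one, gave as many, 289 against at most 2 in the others. Every other split mixes the 2 groups, so a group difference widens the spread within its sides, which lowers its calls. Part of that difference can also remain in the list tests of such splits. The splits cannot exclude a chance difference between cultures or sessions, since the arrays of a group may share either. For the number of lists, 2 of 100 splits, the real one included, stood at 7 or more, a share under 0.05. The highest of the other splits also passed 7 and 65 of these 99 passed at least 1, so any single list passing camera is weak evidence. An array session or scan that ran with the group cannot be told apart from lenvatinib, because the dimmest lenvatinib blanks were 1.79 times the brightest control blanks. Within groups, blank brightness and position along the treatment direction correlated at r = 0.62 over all arrays (exact permutation p = 0.164). With the point of lenvatinib replicate 5 left out, r was -0.65 (exact permutation p = 0.195), though that array still entered the positions of the others. These values leave an array session or scan open, and an effect of lenvatinib itself stays open too.

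Lenvatinib replicate 5 had the brightest blanks of its group (85.5), the brightest second spike control (30079) and the highest median signal (34.7). Its log2 values were the lowest of the group for miR-130b-3p (6.93), miR-146a-5p (3.48), miR-6765-3p (6.16), miR-590-5p (2.24), miR-140-5p (4.10), miR-30e-5p (5.31), miR-29c-3p (4.40), miR-21-5p (11.35), miR-122-5p (12.47), miR-193b-3p (7.03), miR-16-5p (12.14), miR-215-5p (8.60), miR-3180-3p (3.02), miR-4787-3p (2.23) and miR-19a-3p (7.30). They were the highest for miR-34a-5p (7.27), miR-424-5p (9.47), miR-6768-5p (6.98), miR-642a-3p (7.92) and miR-3960 (12.04). It lay at 19.2 on the first principal component, which it helped to define, against 5.75 to 7.37 for the other 4, and 14 of the 20 miRNAs listed lay further out than these 4 in the direction of their difference from the controls. The tracked miRNAs were mostly chosen by change or p with this array included, which favours miRNAs that it pushes outward. A stronger response in the same direction as the whole of its deviation is argued against by a correlation over probes of at most 0.11 between that deviation and the treatment difference of other arrays, where this difference correlated at 0.49 to 0.74 between separate arrays. Of 334 miRNAs that passed without it and had a value on it, it lay beyond the other 4 lenvatinib arrays for 138 and short of all 4 for 122. Each of the other 4, when left out in the same way, lay beyond for 17 to 32 and short for 46 to 72. Their comparison arrays included lenvatinib replicate 5, whose outlying values widen the range, so their counts are not strictly comparable with 138 and 122. A noisier array alone would raise both counts and bring them closer together, so these counts cannot decide whether it leans outward. The calls did not rest on this array, since 336 miRNAs passed without it. What sets it apart stays open, a stronger response as part of it included, and no biological explanation was tested.

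On control arrays, replicate 5 was highest for miR-224-3p (6.68) and miR-1185-1-3p (2.59) and lowest for miR-21-5p (12.48) and miR-107 (10.97). Control replicate 4 was lowest for miR-122-5p (12.04) and miR-23a-3p (10.43) and highest for miR-1290 (2.85) and miR-642a-3p (6.003). Control replicate 2 was highest for miR-3651 (8.64), and lenvatinib replicate 1 was lowest for miR-1290 (2.91).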

How the results depend on the processing

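Scaling to the spike controls, the authors' global normalization and keeping the NG spots were chosen only after the result was seen. Calls numbered 226 to 336 on leaving out 1 array (share higher 54.8% to 60.6%, lists 6 to 8, difference in detected miRNAs -78.85 to 11), and 249 to 393 in the other alternatives but for no scaling. With no scaling 930 miRNAs passed, 99.8% of them higher, because the lenvatinib arrays were brighter. The share was 31.9% after scaling to the 75th percentile and 69.1% after scaling to the spike controls. Lists past the threshold numbered 4 after scaling to the median, 4 to the 75th percentile, 3 with no scaling, 4 with the authors' normalized table, 4 with the authors' global normalization, 0 with an estimated correlation and 11 with fry. The number of detected miRNAs per array turned to a difference of 405.8 with 1 raw limit for all arrays, by construction, since lenvatinib arrays were brighter. MiR-122-5p turned to -0.043 after scaling to the median, -0.20 to the 75th percentile and -0.030 with the authors' global normalization, and miR-107 to -0.083 after scaling to the 75th percentile. With no scaling these turned positive: miR-140-5p 0.19, miR-3651 0.15, miR-30e-5p 0.27, miR-885-5p 0.28, miR-29c-3p 0.48, miR-487b-3p 0.28, miR-21-3p 0.35, miR-106b-3p 0.42, miR-452-5p 0.38, miR-17-3p 0.65, miR-378a-3p 0.68, miR-29a-3p 0.62, miR-18a-5p 0.63, miR-29b-1-5p 0.73, miR-19b-3p 0.38, miR-497-5p 0.69, miR-21-5p 0.37, miR-455-5p 0.98, miR-30a-3p 0.93, miR-221-3p 0.93, let-7a-5p 1.40, miR-301b-3p 0.22 and miR-19a-3p 0.10. Apart from what the constructions show, the cause was not tested. With the replicate block 257 miRNAs passed, 241 of them shared with the 289, and all 7 lists, and the difference in detected miRNAs had a p of 0.438 in the exact sign-flip test. Of the 69 tracked miRNAs, 6 lost their call with the block, miR-590-5p, miR-30a-3p, miR-122-5p, miR-107, miR-200a-3p and miR-365a-5p (limma adjusted p from 0.0506 to 0.0799). After each group's mean was subtracted from every probe, the deviations of same-numbered control and lenvatinib arrays correlated at 0.114, 0.116, 0.140, 0.135 and 0.0008. So 4 of 5 lay over 0.1 and replicate 5 did not, and 3 of 5 matched best with their own number. Because pairing was to be taken only where all 5 lay over 0.1, the arrays were not paired. A block for slide or scan date was not run, as the files used here give neither, and the rank test was not applied to lists. Signal over background limits the dim miRNAs, as 41 of 69 changes shrank by over 1.5 times with normexp background correction and 40 with none, miR-224-3p to -0.39.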

Other observations

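The test of neighbouring miRNA genes and the pairs named here were chosen only after the results were seen. Several miRNAs whose genes lie next to each other changed in the same direction. MiR-224-5p and miR-452-5p, which lie within GABRE, changed by -1.5 and -0.93 on the log2 scale, miR-301b-3p and miR-130b-3p by -1.02 and -1.70, and miR-18a-5p and miR-19a-3p by -0.74 and -1.30. MiR-193b-3p and miR-365a-5p changed by 0.82 and 0.55, miR-503-5p and miR-424-5p by 0.52 and 0.54, and miR-3960 and miR-2861 by 1.28 and 0.65. All of these passed an adjusted p of 0.05 in limma under the main settings, but the call of miR-365a-5p held in 20 of 27 alternatives and that of miR-2861 in 24 of 27.

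Shared primary transcripts may contribute to this pattern. Over 106 pairs of neighbouring miRNA genes at most 10000 bases apart, among 918 miRNAs with 1 place in the genome, the log2 fold changes differed by 0.516 on average. Random pairings matched on level had a median of 0.610 and a lowest 5% at 0.533 (one-sided permutation test, 10000 permutations, p = 0.0238). Pairs were formed by position alone, without regard to strand. Genes on opposite strands share no primary transcript, so the test cannot isolate shared transcripts. In 7 pairs both miRNAs passed in the same direction and in 3 in opposite directions, and 65 of 106 pairs had the same sign. The 3 were miR-192-5p (0.45) with miR-6750-3p (-0.52), miR-6750-3p with miR-6749-5p (0.52), and miR-1185-1-3p (2.02) with miR-487b-5p (-0.65). Beside miR-18a-5p and miR-19a-3p, their neighbours miR-17-5p (-0.20) and miR-20a-5p (-0.12) did not pass. Probes of neighbouring miRNAs with similar sequences could add to the likeness and were not set apart.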
